A study of Mus musculus with 3 samples.

How the data were processed

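PolyA plus RNA-seq of mouse regulatory T cells was deposited as 3 libraries, which the labels number as technical replicates 1, 2 and 3 of biological replicate 1. Per the labels, RNA was sheared before library construction and the files refer to the mm10 assembly. Each deposited file holds a gene identifier and a whole-number count for 22457 genes, quantified with GENCODE M4 per the file descriptions that accompany the libraries. The aligner, the counting program, the strand setting and any removal of duplicate reads are not given in the sources used here. Without a stated strand setting, counts of overlapping and antisense genes cannot be separated, and genes with near-identical copies (globins, processed-copy families, immunoglobulin constant and V genes) are uncertain.

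Gene names, positions, types and coding lengths were taken from GENCODE M21, which annotates the same assembly (GRCm38). Coordinates are therefore those of M21 gene models, while the counts used M4 models. Of the identifiers 22195 matched and 262 did not, and the unmatched ones held 0.117% of the counts. Coding sequences were known for 21784 genes, which held 99.8% of the counts. A set of 26 gene lists with 281 entries was fixed before the data were examined, and 276 entries matched. The 5 others were Trdc, Trgc1, Trgc2 and Trgc4 of the gamma delta T cell list and Xist of the sex-linked list. The symbols held by more than 1 list were 2, Il2ra and Gata3.

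The design foresaw TPM and allowed CPM where counts alone were given. CPM by total count was used for levels, marker ratios, detection and the shares of gene classes, so that values of different genes are not corrected for length. Totals were 3206781, 3228215 and 2872350 counts, and 1 CPM equalled 3.21, 3.23 and 2.87 counts. Shares of single libraries carry 95% exact binomial intervals, and counts of 0 were read against a floor of 3 counts per library. The group was not compared with another, since the labels give 1 group.

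Differences between the libraries were tested per gene with Pearson's chi-square of the 3 counts against Poisson expectation with 2 degrees of freedom. Library sizes were totals times TMM factors (0.990, 1.02 and 0.993) from edgeR 4.0.16 in R 4.3.3, genes needed a mean count of at least 10, and p-values were adjusted by Benjamini-Hochberg at 0.05. Pairs of libraries were compared gene by gene with a 2-sided exact binomial test conditional on the sum, by doubling the smaller tail. The labels call the libraries technical replicates of 1 biological replicate, and p-values measure the spread between these libraries, not that between animals. The tests were tried on simulated Poisson counts with 200 genes among 10282 changed in library 2. The simulation had no extra spread and no limit on counts per coding base, so it does not show how the tests behave with these. The chi-square test called 16.0%, 58.0%, 84.0% and 100% of the genes changed by 1.25, 1.5, 2 and 4 fold, and 3 of 10082 unchanged genes. For each list the median CPM was set against 10000 random lists of the same size, as a description without a p-value.

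Genes were named by a rule fixed before the data were examined. It took Foxp3, Cd4, Cd8a and Cd3e, the 4 members of each list with the highest mean level (8 for the core list), members of regulatory T cell lists under 1 CPM by name only, the 15 most abundant genes, the 10 most variable genes past the chi-square test with a mean count of at least 100, and the genes of the marker ratios. Other names were chosen after their values were seen, and the text says so. Some genes that the rule takes, and 1 of the marker ratios, are not reported here.

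Alternatives were DESeq2 1.42.0 size factors, plain totals, other count filters, a negative binomial model with the common dispersion of edgeR, other thresholds, other pools of random lists, pseudocounts of 0.1 and 1 CPM, thinning to the smallest library, and leaving out each library. Levels divided by coding length, a restriction to genes with 0.5 or fewer counts per coding base, and removal of trends with coding GC content and coding length were added after the data were seen. The counts of list members and of gene types under the negative binomial model and under the other scalings were also made after the data were seen. A percentile was held to be the same within 5 points and a count within 1.5 fold. Medians of lists, log2 ratios of marker genes and shares were held to be the same within their SD over the 3 libraries. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.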

Results

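The transcriptome of mouse regulatory T cells was profiled by polyA plus RNA-seq. Regulatory T cells are the CD4 T cells that hold other immune cells in check, and the transcription factor Foxp3 marks them. The cells were primary cells of adult mice aged 4 months, which the labels describe as derived from haematopoietic cells of the bone marrow. The labels give 3 libraries, all technical replicates of 1 biological replicate, so that there was 1 group and no comparison between conditions. The total gene count was 3206781 in library 1, 3228215 in library 2 and 2872350 in library 3. Levels are given in CPM, counts scaled to a total of 1000000 per library, as mean ± SD over the 3 libraries (n = 3 throughout), and the SD is the spread between these libraries, which says nothing of the spread between animals. At this depth 3 counts corresponded to 0.936, 0.929 and 1.04 CPM in libraries 1, 2 and 3. Intervals and floors cover counting error only. In all 3 libraries 10866 of 22457 genes reached 1 CPM, and 7345 genes had no count in any library.

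The first question was whether the libraries carried the transcripts that define the labelled cell type. Foxp3, the lineage transcription factor of regulatory T cells, was present in every library at 142, 157 and 150.4 CPM (455, 507 and 432 counts). The gene lies on chromosome X at 7573644 to 7595245 on the plus strand (ENSMUSG00000039521.8, GRCm38, GENCODE M21 gene model). Cd4, the co-receptor of helper and regulatory T cells, stood at 551 ± 60.5 CPM (chromosome 6, 124864692 to 124888221, minus strand, ENSMUSG00000023274.10). Cd8a, the co-receptor chain of cytotoxic T cells, stood at 7.03 ± 3.61 CPM, with 14, 18 and 32 counts (chromosome 6, 71373427 to 71379173, plus strand, ENSMUSG00000053977.9). Cd3e, a chain of the T cell receptor complex, reached 395 ± 13.4 CPM (chromosome 9, 44998740 to 45009627, minus strand, ENSMUSG00000032093.6). Foxp3 and Cd3e did not differ between the libraries beyond counting error (chi-square test against Poisson, adjusted p = 0.623 and 0.249), whereas Cd4 was highest in library 1 and Cd8a in library 3 (adjusted p = 4.86e-09 and 0.0163, same chi-square test). Cd3e lies near a limit of counts per coding base (2.16), where counts did not follow depth.

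Genes of the regulatory T cell program were among the most abundant lists. All 22 members of the core list reached 1 CPM in every library, from 5.39 to 828 CPM, with a median of 325 CPM. The highest were Nrp1, a semaphorin receptor, at 828 ± 67.2 CPM, Izumo1r, which encodes folate receptor 4, at 619 ± 11.8 CPM and Nt5e, which encodes the ecto-nucleotidase CD73, at 564 ± 75.4 CPM. They were followed by Tnfrsf18 (GITR) at 521 ± 18.5 CPM, the actin-capping gene Capg at 509 ± 6.81 CPM, Tnfrsf4 (OX40) at 501 ± 20.8 CPM, the integrin gene Itgae (CD103) at 463 ± 64.0 CPM and Il2ra, the alpha chain of the IL-2 receptor, at 386 ± 46.8 CPM. The list's median lay above all 10000 random lists of 22 genes drawn from the genes with a count (percentile 100). This percentile is not particular to the list. The pan T cell, resting or naive T cell and housekeeping lists also lay at percentile 100, and the cell cycle list at 99.9. Without library 3 the median was 311 CPM.

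Effector and tissue regulatory T cell genes were detected as a whole, and suppressive effectors nearly so. All 14 effector or tissue members reached 1 CPM in every library, with a median of 109 CPM (percentile 99.8). Gata3, a transcription factor, stood at 331 ± 46.4 CPM, and the chemokine receptor genes Cxcr3, Ccr8 and Ccr6 at 265 ± 24.3, 178 ± 24.6 and 139.8 ± 6.73 CPM. Of 12 suppressive effectors 11 reached 1 CPM in every library (median 62.8 CPM, percentile 94.5). The inhibitory receptor gene Pdcd1 led them at 245 ± 35.7 CPM, ahead of the galectin gene Lgals1 at 237 ± 13.0 CPM, Lag3 at 92.7 ± 18.5 CPM and Cd274, which encodes PD-L1, at 85.5 ± 5.26 CPM. Il12a, which encodes a subunit of IL-35, was the member with a mean under 1 CPM. All 12 genes of IL-2 receptor signalling reached 1 CPM, with a median of 182 CPM and Jak1 (1435 ± 82.3 CPM), Il2rb (875 ± 56.5 CPM), Il2ra and Il2rg (225 ± 13.6 CPM) at the top.

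Transcripts shared by T cells were abundant, while cytokines of conventional helper cells were close to the floor. The 20 pan T cell genes had the highest median of all lists, 391 CPM, led by the kinase gene Lck at 1006 ± 46.5 CPM, Cd6 at 894 ± 37.5 CPM, Ptpn22 at 828 ± 24.0 CPM and Cd2 at 680.4 ± 34.7 CPM. All 10 genes of resting or naive T cells were present with a median of 327 CPM, including Foxp1 (484 ± 5.57 CPM), the homing receptor gene Ccr7 (385 ± 17.6 CPM) and the IL-7 receptor gene Il7r (467 ± 66.1 CPM). The CD4 lineage list had a median of 289 CPM, with Tox at 512 ± 24.5 CPM, Cd40lg at 65.4 ± 3.71 CPM and Zbtb7b at 46.7 ± 0.956 CPM beside Cd4. Of the 12 helper cytokine genes 3 reached 1 CPM in every library, and the list's median was 0.207 CPM. Tnf stood at 20.3 ± 2.33 CPM, Ifng at 6.81 ± 2.42 CPM, Il4 at 2.64 ± 1.17 CPM and Il21 at 1.28 ± 0.504 CPM, and Il2 had 1, 2 and 0 counts. The helper lineage transcription factors were higher (median 67.9 CPM, 7 of 7 members), with Stat6 at 679 ± 49.96 CPM, Stat4 at 520.0 ± 17.1 CPM and Bcl6 at 67.9 ± 11.4 CPM beside Gata3.

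Other T lineage lists were low. The CD8 lineage list had a median of 7.03 CPM, with Cd8b1 at 26.7 ± 2.89 CPM, Runx3 at 7.82 ± 3.67 CPM and Gzmk at 2.16 ± 0.290 CPM beside Cd8a. All 5 of its members reached 1 CPM in every library, and 1 reached 5 CPM. Of 6 immature thymocyte genes 3 reached 1 CPM, namely Themis at 154 ± 23.3 CPM, Cd1d1 at 82.6 ± 1.30 CPM and Dntt at 3.50 ± 2.07 CPM. Rag1, which encodes a recombinase of receptor gene assembly, had no count in any library. The gamma delta T cell list could be judged only by Sox13, which also had no count, because its other 4 entries were not matched.

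Markers of other blood and tissue cells were measured the same way and served as the background. B cell genes were all present, with a median of 51.6 CPM (percentile 89.3). Ighm, the IgM heavy chain gene, reached 985 ± 42.5 CPM, Igkc, the kappa light chain gene, 233 ± 11.7 CPM, Cd79b 91.6 ± 17.2 CPM and Ms4a1, which encodes CD20, 56.3 ± 23.8 CPM. Antigen presentation genes led the dendritic cell list, with Cd74 at 482 ± 52.0 CPM, H2-Aa at 147 ± 57.0 CPM, H2-Ab1 at 132 ± 44.9 CPM and H2-Eb1 at 107 ± 38.8 CPM, but B cells also express these genes and the list's median was 3.84 CPM. Of 6 plasma cell genes 4 reached 1 CPM in every library, led by Igha (122 ± 167 CPM), Jchain (64.7 ± 49.0 CPM), Xbp1 (63.1 ± 6.83 CPM) and Mzb1 (12.4 ± 3.52 CPM). The NK cell list had a median of 5.23 CPM, with Ccl5 at 132 ± 15.7 CPM and Nkg7 at 116 ± 14.03 CPM above Prf1 (27.1 ± 2.35 CPM) and Gzma (10.7 ± 8.27 CPM). Monocyte and macrophage genes had a median of 6.07 CPM, and the highest were Ms4a6c at 48.4 ± 9.24 CPM, Csf1r at 12.5 ± 5.73 CPM, Cd68 at 11.6 ± 4.45 CPM and Lyz2 at 9.48 ± 3.52 CPM.

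Neutrophil and erythroid genes were seen mainly in libraries 2 and 3. No member of the 12-gene neutrophil list reached 1 CPM in every library, but 5 did once library 1 was left out and 1 once library 2 was left out. Ngp (10.4 ± 16.8 CPM) and Camp (4.03 ± 6.19 CPM) encode granule proteins, and S100a8 (9.23 ± 12.8 CPM) and S100a9 (3.81 ± 4.65 CPM) encode the subunits of calprotectin. Of 10 erythroid genes 2 reached 1 CPM in every library and 9 did without library 1. Hbb-bs, a beta globin gene, stood at 34.1 ± 29.5 CPM, the haem synthesis gene Alas2 at 29.2 ± 19.3 CPM, Hbb-bt at 23.1 ± 20.2 CPM and the alpha globin gene Hba-a1 at 18.5 ± 16.1 CPM. The globin genes occur as near-identical copies, so their split within each pair is uncertain. Haematopoietic progenitor genes had a median of 0.168 CPM, with Ly6a, which T cells also express, at 163 ± 13.5 CPM and Kit, Meis1 and Procr at 4.81 ± 0.566, 0.633 ± 0.525 and 0.219 ± 0.191 CPM. Megakaryocyte and platelet genes had a median of 0.116 CPM, with Itga2b at 3.50 ± 1.80 CPM, Pf4 with 2 counts in library 3, and Ppbp with 1 count there. The stroma and endothelium list had a median of 0.266 CPM, with Pecam1, which leukocytes also carry, at 361 ± 47.6 CPM, Vcam1 at 24.1 ± 2.90 CPM and the collagen genes Col1a1 and Col3a1 at 1.18 ± 0.327 and 0.336 ± 0.349 CPM.

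**Figure D1:**
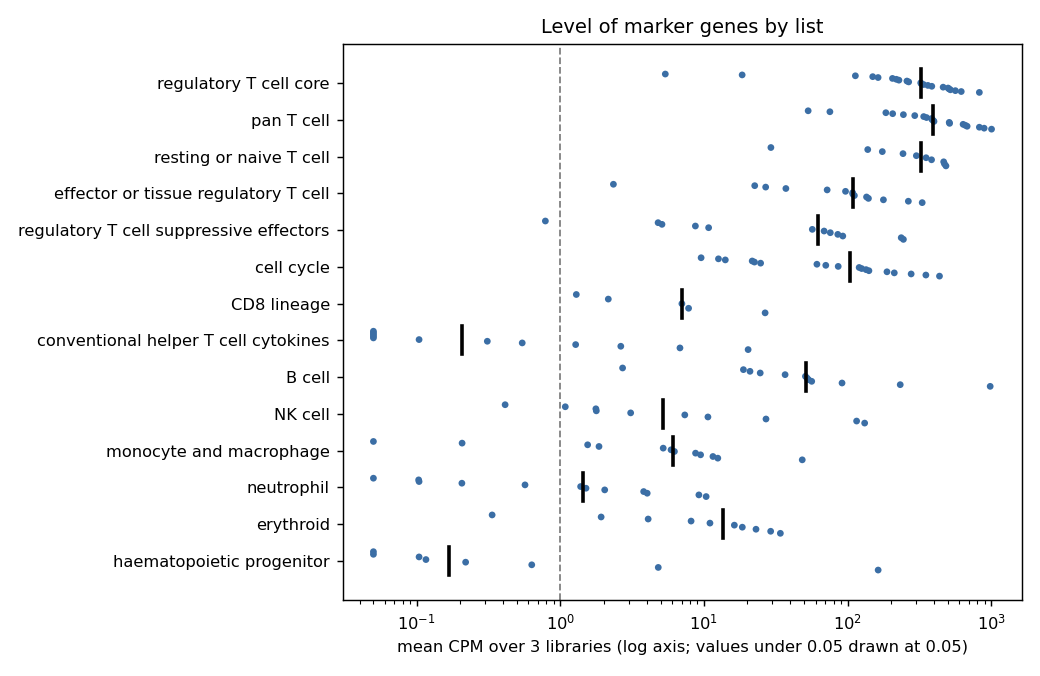
Level of marker genes by list. Each point is a gene at its mean CPM over the 3 libraries (log axis), the black bar is the list's median and the dashed line marks 1 CPM. The regulatory T cell core list has a median of 325 CPM, and the helper cytokine list of 0.207 CPM.

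Housekeeping and cell cycle genes were present in every library. The 12 housekeeping genes had a median of 239 CPM, with Sdha at 699 ± 33.1 CPM, Actb at 622 ± 39.6 CPM, Tubb5 at 440.1 ± 20.6 CPM and B2m at 278 ± 16.5 CPM. Gapdh, Ppia and Pgk1, chosen after their values were seen, stood at 9.61 ± 1.57, 14.03 ± 1.48 and 5.87 ± 0.972 CPM. These genes have near-identical processed copies in the genome, and their counts are uncertain. All 18 cell cycle genes reached 1 CPM in every library (median 103 CPM), including the replication helicase genes Mcm6 (437 ± 18.9 CPM), Mcm4 (351 ± 20.2 CPM) and Mcm3 (212 ± 17.0 CPM) and the topoisomerase gene Top2a (277 ± 59.4 CPM). Immediate early genes had a median of 30.1 CPM, and Zfp36, Nr4a1, Dusp1 and Egr2 stood at 329 ± 21.99, 234 ± 22.6, 126 ± 19.7 and 118 ± 11.2 CPM. The sex of the animals was not recorded, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were present in every library at 354 ± 60.4, 292 ± 47.4, 275 ± 33.95 and 169 ± 11.7 CPM.

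The most abundant gene was Ptprc, which encodes the leukocyte antigen CD45, at 2207 ± 144 CPM, followed by the cytoskeletal linker gene Macf1 (2009 ± 67.3 CPM), Dock2 (1730.3 ± 50.2 CPM) and the condensin gene Smc4 (1730.0 ± 41.7 CPM). Eif4g2, Sf3b1, Arhgap45, Flna, Jak1, Eef2, Utrn, Myh9, Atrx and Akap13 were among those that came next, between 1573 and 1211 CPM. The 10 most abundant genes took 1.66 ± 0.0521% of the counts and the 100 most abundant 9.48 ± 0.189%. Ribosomal protein genes took 0.599 ± 0.0323%, the 13 mitochondrially encoded genes 0.390 ± 0.0211% and histone genes 0.0168 ± 0.00328%. CPM is not corrected for gene length, and with levels divided by coding length the ribosomal protein share was 1.43% and the histone share 0.0527%. Unscaled counts of ribosomal protein genes (18523, 18834 and 18276 in libraries 1, 2 and 3) hardly followed depth. Those of mitochondrially encoded genes (12064, 12246 and 11900) hardly did either. A limit on counts per coding base, described below, could understate shares of genes near it and change the order of the most abundant genes. Shares and CPM rest on the total, so it could in turn overstate genes far below it. The 65 histone genes together held 452, 660 and 456 counts in libraries 1, 2 and 3.

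A group of genes lay close to a common limit of counts per base of coding sequence. Among genes with a coding length of at least 1000 bases the highest value was 2.12 counts per coding base, and Lck stood at 2.00, Ighm at 2.05, Ptprc at 1.76 and Actb at 1.70. The shorter genes Cd3e and B2m stood at 2.16 and 2.41, while Foxp3 stood at 0.361 and Cd4 at 1.251. Among genes of at least 300 coding bases, 21 exceeded 2 counts per coding base, up to 2.56. Of the 15 most abundant genes 4 had 1.6 or more counts per coding base, and Macf1, Utrn and Akap13 were far lower at 0.231, 0.406 and 0.436. In the 86 genes at 1.6 or more counts per coding base, the median log2 ratio of library 3 to library 1 was -0.03 in unscaled counts. Genes under 0.2 counts per coding base had a median of -0.20 (SE of the difference 0.0093), and the log2 ratio of the library totals was -0.16. In CPM, genes near the limit therefore came out higher in the shallowest library.

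**Figure D2:**
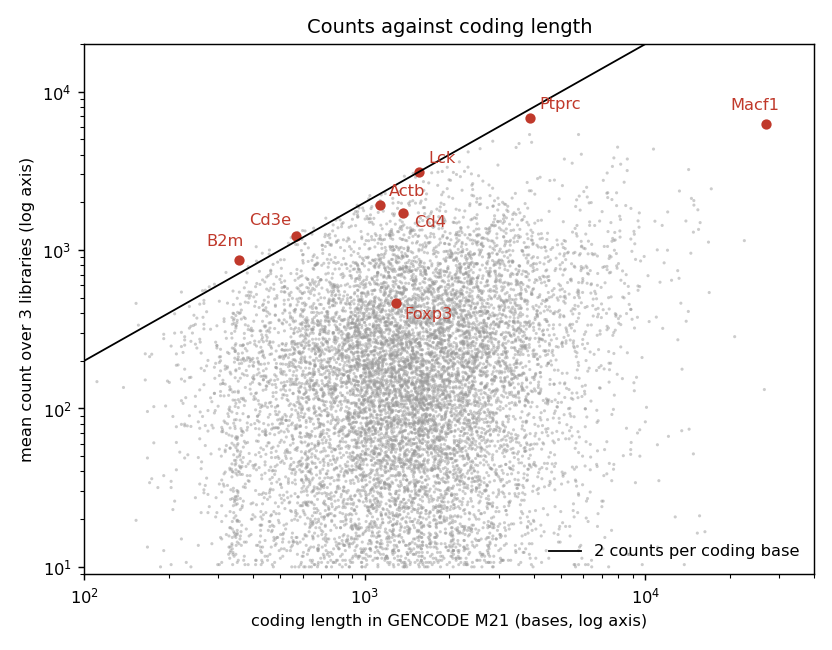
Counts against coding length. Each grey point is a gene at its mean count over the 3 libraries (vertical log axis) and its coding length in bases in GENCODE M21 (horizontal log axis), and the line marks 2 counts per coding base. Lck, at 2.00 counts per coding base, lies on the line, B2m, at 2.41, above it and Foxp3, at 0.361, below it.

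Ratios between marker genes were taken within each library, so the total used for scaling cancels. They can still shift with depth where 1 gene lies nearer the limit of counts per coding base. In genes at 1 to 1.6 counts per coding base, the median log2 ratio of library 3 to library 1 was -0.062 in unscaled counts. It was -0.21 in genes under 0.1 counts per coding base. Cd4, Il2ra and Il7r lie in the first range and Cd8a in the second. Cd4 to Cd8a could therefore be understated. Cd4 exceeded Cd8a by 6.41 ± 0.84 on the log2 scale, with 7.15, 6.58 and 5.49 in libraries 1, 2 and 3. Foxp3 exceeded Il2 by 7.27 ± 0.12 with Il2 set to the floor of 3 counts per library. Against this fixed floor the value follows library depth, and its SD is the spread of the Foxp3 counts alone. The pooled counts, 1394 against 3, gave 8.86 (95% exact binomial interval 7.31 to 11.1). Once levels were divided by coding length these ratios were 5.52 for Cd4 to Cd8a and 5.93 for Foxp3 to Il2 at the floor. Division by exon length was not tried, and the part of each gene that was counted is not known. Cd4 and Cd8a have coding lengths of 1371 and 741 bases and exon lengths of 4032 and 3637 bases. Il2ra lay below Il7r (-0.27 ± 0.08), and the transcription factor gene Ikzf2 (Helios) below Ikzf4 (Eos) (-0.16 ± 0.12). Both of these small ratios changed sign with levels divided by coding length, to 0.39 and 0.26. No p-value is given, since a sign test over 3 libraries cannot go below 0.25.

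The remaining question was whether the technical replicates differed by more than counting error. Genes of the regulatory T cell core list that passed differed by 1.34-fold or less, whereas some genes of B cells, plasma cells, neutrophils and erythroid cells differed by larger factors. The core gene Plagl1, chosen after its values were seen, did not pass (adjusted p = 0.0889, chi-square test). It had 25, 18 and 8 counts, and its highest library exceeded its lowest by 2.81-fold in scaled counts. In a chi-square test of the 3 counts of each gene against Poisson expectation, 2836 of 10282 genes (27.6%) passed a Benjamini-Hochberg adjusted p of 0.05, and 3971 had an unadjusted p under 0.05. Of the 2836 genes, 1143 were highest in library 1, 896 in library 2 and 797 in library 3, and with plain totals as library sizes these numbers were 984, 1186 and 697. The ratio of the highest to the lowest library was 1.5 or more in 1026 of them and 2 or more in 414. With a negative binomial model that allowed a coefficient of variation of 12.5% common to all genes, 93 genes passed, and all of these were among the 2836. The 12.5% was estimated from the same 3 libraries, so the model marks only genes that vary more than is typical between them. Leaving out library 2 lowered the Poisson count to 957 and leaving out library 1 to 1686.

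Most B cell genes were highest in library 3, and the plasma cell genes that differed were highest in library 2. Of 11 B cell genes tested 9 passed, all highest in library 3 (9 adjusted over the list alone). Ms4a1 was 2.21-fold higher in library 3 than in library 1 (95% exact binomial interval 1.77 to 2.77, adjusted p = 2.15e-12, chi-square). Ighm, among the 9, differed by 1.11-fold in the scaled counts, though its unscaled count was lowest in library 3 (3097, 3082 and 2968). Igkc did not pass (adjusted p = 0.507, chi-square), but it and Ighm lie near the limit of counts per coding base (2.26 and 2.05), where counts did not follow depth. H2-Aa was 2.14-fold higher in library 3 than in library 1, and it was among the 6 of 7 dendritic cell genes that passed, all highest in library 3 (7 adjusted over the list alone). Of 4 plasma cell genes tested 2 passed, Igha and Jchain, both highest in library 2 (2 adjusted over the list alone). Igha had 4, 1007 and 149 counts, a 250.1-fold difference between libraries 2 and 1 (97.4 to 919.6), and Jchain differed 4.20-fold (3.34 to 5.33). With the negative binomial model, 39 of 49 immunoglobulin genes, 3 B cell genes, 2 dendritic cell genes and both plasma cell genes still passed.

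Neutrophil and erythroid genes differed by larger factors than Ms4a1. All 4 neutrophil genes tested passed and were highest in library 2, and all 8 erythroid genes tested passed, 6 highest in library 2 and 2 in library 3 (4 and 8 adjusted over the list alone). Ngp had 1, 96 and 3 counts, which put library 2 95.4-fold above library 1 (16.7 to 3805). S100a8 had 0, 77 and 11 counts, at least 25.5-fold above library 1 and 6.23-fold above library 3 (3.29 to 13.0). Hbb-bs had 0, 167 and 145 counts, so libraries 2 and 3 were at least 55.3-fold and 54.0-fold above library 1. The globin genes did not separate library 2 from library 3. Library 2 was 1.02-fold (0.815 to 1.29) and 1.18-fold (0.894 to 1.57) above library 3 for Hbb-bs and Hbb-bt, and library 3 1.08-fold (0.792 to 1.48) and 1.02-fold (0.731 to 1.43) above library 2 for Hba-a1 and for Hba-a2, which was chosen after its values were seen. Alas2 was 5.80-fold higher in library 2 than in library 1 (3.78 to 9.26). All 4 neutrophil and all 8 erythroid genes also passed with the negative binomial model.

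Genes of the regulatory T cell lists also differed between the libraries. Of 22 core genes 9 passed, 5 highest in library 1, 2 in library 2 and 2 in library 3 (10 adjusted over the list alone), and 12 had an unadjusted p under 0.05. For comparison, 2386 of 6284 genes passed when those with a mean count of at least 100 were tested. With the negative binomial model no core gene passed, and none had an unadjusted p under 0.05. This means that they varied no more than that model allows, not that they agree between the libraries. The highest library exceeded the lowest by 1.17-fold for Nrp1, 1.34-fold for Nt5e, 1.33-fold for Itgae and 1.30-fold for Il2ra. Izumo1r, Tnfrsf4 and Tnfrsf18, which did not pass, lie near the limit of counts per coding base (2.04, 1.90 and 1.71). Of 13 effector or tissue genes tested 6 passed (9 adjusted over the list alone), and of 11 suppressive effectors 4 passed (5 adjusted over the list alone). Tgfb1, Myb, Gzmb and Tyrobp were chosen after their values were seen. Tgfb1, a suppressive effector with 40, 15 and 26 counts, was 2.68-fold higher in library 1 than in library 2 (1.45 to 5.23), and Myb, an effector or tissue gene, 1.67-fold higher in library 3 than in library 2 (1.17 to 2.38). Gzmb, a suppressive effector that encodes granzyme B, was 2.54-fold higher in library 3 than in library 1 (2.00 to 3.23). It was the single regulatory T cell list member that passed with the negative binomial model. The NK cell genes Gzma (17, 21 and 58 counts) and Tyrobp (11, 22 and 34 counts) were also highest in library 3, at 3.81-fold (2.19 to 6.98) and 3.45-fold (1.71 to 7.55) above library 1. Among IL-2 receptor signalling genes 8 of 12 passed (10 adjusted over the list alone) and none with the negative binomial model, in which 1 had an unadjusted p under 0.05. Il2rb, among the 8, had nearly level unscaled counts (2711, 2707 and 2699) and lies near the limit of counts per coding base (1.67).

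The other lists differed in part. Of 20 pan T cell genes 11 passed (11 adjusted over the list alone), 7 of them highest in library 3, but 6 passed with plain totals as library sizes. Lck and Cd2 were among those highest in library 3 and lie near the limit of counts per coding base. Of 10 resting or naive genes 4 passed, all highest in library 3 (5 adjusted over the list alone). The CD4 lineage list had 2 of 4 genes past the test, both highest in library 1, the CD8 lineage list 2 of 3 and the helper transcription factors 3 of 7 (2, 2 and 3 adjusted over the list alone). Cell cycle genes passed in 8 of 18 cases (11 adjusted over the list alone), 3 highest in library 1, 5 in library 2 and none in library 3, with Top2a 1.51-fold higher in library 1 than in library 3 (1.37 to 1.67). NK cell genes passed in 4 of 5 cases, 3 highest in library 3, and monocyte and macrophage genes in 5 of 8, 4 highest in library 3 (4 and 7 adjusted over the list alone). Housekeeping genes passed in 2 of 12 cases, immediate early genes in 5 of 12, immature thymocyte genes in 1 of 3, stroma and endothelium genes in 1 of 2 and Y-linked genes in 3 of 4 (2, 6, 2, 1 and 4 adjusted over the list alone). Actb, a housekeeping gene that passed, had nearly level unscaled counts (1926, 1930 and 1918) and lies near the limit of counts per coding base. None passed of 2 helper cytokine, 2 progenitor and 1 platelet gene tested, and none of these had an unadjusted p under 0.05 in the chi-square test. With the negative binomial model 1 NK cell gene, Gzma, passed in these lists.

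**Figure D3:**
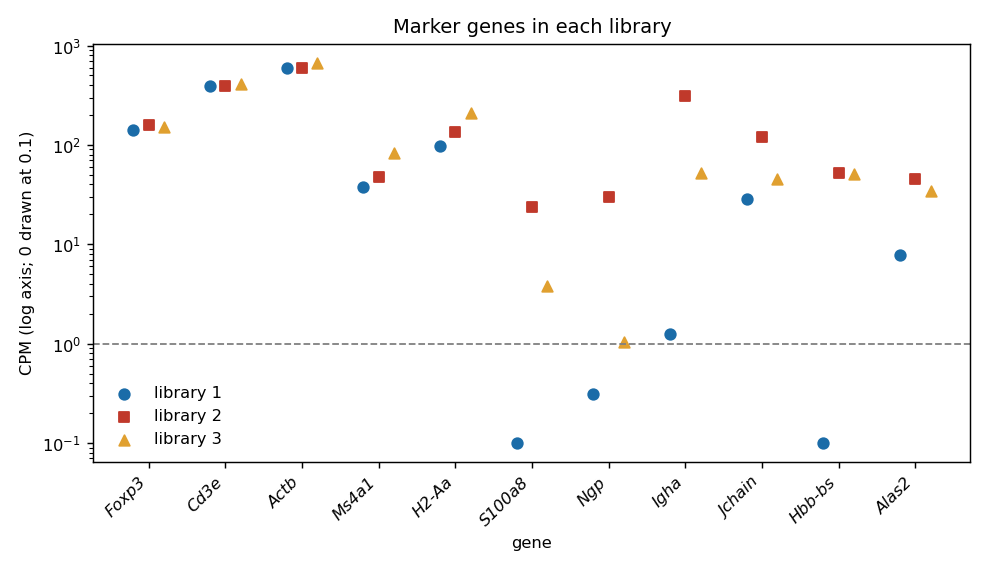
Marker genes in each library. Points give the CPM (log axis, 0 drawn at 0.1) of 11 genes in libraries 1, 2 and 3, and the dashed line marks 1 CPM. Foxp3 lies between 142 and 157 CPM in all libraries, while Igha has 4 counts in library 1 and 1007 in library 2.

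The 10 most variable genes were led by the antibody and globin genes. These were chosen by the SD of log2 CPM among the 2230 genes that passed the chi-square test with a mean count of at least 100. Igkv5-39, a kappa V gene on chromosome 6 (69900424 to 69900977), had 0, 375 and 143 counts and an SD of 5.19. Hbb-bs (chromosome 7, 103826534 to 103828096) and Igha (chromosome 12, 113254830 to 113260236) followed with SDs of 4.83 and 3.97. Igkv19-93 (chromosome 6, 68736297 to 68736780) was 23.3-fold higher in library 1 than in library 2 (13.4 to 44.3), and Ighg2c, an IgG heavy chain gene (chromosome 12, 113285325 to 113288932), 31.4-fold higher in library 3 than in library 2 (16.8 to 66.1). Blm, a DNA helicase gene (chromosome 7, 80454733 to 80535119), was 4.72-fold higher in library 1 than in library 2 (3.33 to 6.86). Car2, a carbonic anhydrase gene (chromosome 3, 14886273 to 14900770), was 4.57-fold higher in library 2 than in library 1 (3.28 to 6.52). Jchain (chromosome 5, 88519809 to 88527891) had an SD of 1.06. Cenpf, a mitotic kinetochore gene (chromosome 1, 189640606 to 189688086), was 2.91-fold higher in library 2 than in library 3 (2.18 to 3.94), and Zcwpw1 (chromosome 5, 137787798 to 137822621) 2.59-fold higher in library 3 than in library 2 (1.95 to 3.45). All 10 also passed with the negative binomial model, which is no separate support because they were chosen by their spread in the same counts.

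Taken in pairs, libraries 1 and 3 differed in the fewest genes. Exact binomial tests called 890 of 10282 genes between libraries 1 and 3, 1581 between libraries 2 and 3 and 1908 between libraries 1 and 2. Between libraries 1 and 2, 1155 genes were higher in library 1 and 753 in library 2, and with plain totals as library sizes 943 and 979. Between libraries 2 and 3, 669 were higher in library 2 and 912 in library 3, and with plain totals 812 and 720. Between libraries 1 and 3, 553 were higher in library 1 and 337 in library 3, and with plain totals 532 and 355. With DESeq2 size factors the splits were 1076 and 822 for libraries 1 and 2, 669 and 909 for libraries 2 and 3 and 484 and 388 for libraries 1 and 3. The chi-square statistic per gene was 4.95, 3.21 and 4.34 for pairs 1 and 2, 1 and 3, and 2 and 3, each above the value of 1 for counting error alone, so no library was a copy of another. Across 15112 genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was between 0.984 and 0.985. Spearman's correlation was 0.976 for libraries 1 and 2, 0.976 for libraries 1 and 3 and highest, 0.977, for libraries 2 and 3.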

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

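The alternatives with coding length, with 0.5 or fewer counts per coding base and with GC trends removed were chosen after the results were seen; the others were planned. Of the values that answer a comparison, 88 stayed within the tolerance of their kind under an alternative, 13 moved beyond it and 2 reversed. Of the other list counts 134 stayed within it and 10 moved. For medians, ratios and shares the tolerance is the SD over the libraries, which is not a fixed fold. The number of genes that differ between the libraries fell from 2836 to 93 with a negative binomial model, whose construction allows more spread, and lay between 957 and 2011 with 1 library left out (957 without library 2, 1686 without library 1), where fewer samples are tested. It stayed within 1.5 fold with DESeq2 size factors, plain totals, other count filters, genes with 0.5 or fewer counts per coding base and GC and length trends removed. The median of the regulatory T cell core list was 311 to 327 CPM with 1 library left out. Dividing by coding length moved the log2 ratios of Cd4 to Cd8a to 5.52 and of Foxp3 to Il2 to 5.93. It also reversed Il2ra to Il7r (0.39) and Ikzf2 to Ikzf4 (0.26), since the genes of each ratio differ in coding length. It moved the shares of mitochondrially encoded, ribosomal protein and histone genes to 0.454%, 1.43% and 0.0527%, and of the 10 and 100 most abundant genes to 1.11% and 8.39%. Pseudocounts of 1 and 0.1 CPM gave 6.87 and 8.92 for Foxp3 to Il2, since Il2 lies at the floor. No paired analysis was possible because there was 1 group. Deposited TPM or FPKM values were not available, and the values divided by coding length stood in for them. Depth limits genes near 1 CPM, which rest on about 3 counts per library.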

Other observations

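The tests of a ceiling on counts, all tests of library 2 and the share of differing genes far below the ceiling were chosen after the result was seen.

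Antibody genes differed widely between the libraries. Of 36 immunoglobulin V genes tested, 35 passed the chi-square test, 7 highest in library 1, 19 in library 2 and 9 in library 3. The following genes were chosen after their values were seen. Igkv1-110 had 142, 6 and 6 counts and Ighv4-1 had 207, 0 and 72 in libraries 1, 2 and 3. Igkv4-63 had 2, 193 and 3 counts, Ighv9-4 had 2, 192 and 1, and Igkv4-50 had 0, 160 and 1. Igkv8-24 had 2, 7 and 120 counts. Heavy chain classes parted in the same way, with Igha (IgA) at 4, 1007 and 149 counts, Ighg1 (IgG1) at 1, 0 and 228 and Ighg2b (IgG2b) at 25, 8 and 232, while Ighm (IgM), which lies near the ceiling on counts, had 3097, 3082 and 2968. T cell receptor V genes varied far less, and 8 of 67 passed the test. Trbv17, which had the largest chi-square statistic among them, had 183, 283 and 157 counts.

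More genes differed between the libraries than counting error allows. A trend with GC content and coding length is not the whole cause, because 71.4% of the 2836 genes remained past the test once both trends were removed. Neither is a ceiling on counts per coding base, because 21.4% of 6892 genes under 0.2 counts per coding base passed when tested alone. A candidate explanation is that the libraries were made from separate pools of cells: for antibody-making cells the median statistic of V genes lay at percentile 100 of 10000 random lists matched on mean count (57.9 against 1.41 per degree of freedom), but for T cells it lay at percentile 1.18 (1.02 against 1.61), which speaks against few differing T cell clones. Separate pools of many T cell clones stay open, and no biological difference between animals or conditions was tested, since the design has 1 group.

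Many neutrophil, erythroid and plasma cell genes were highest in library 2, with Igha (1007 counts) and Jchain (389) the most abundant there and Ngp (96) the highest neutrophil gene. Counting error is excluded as the whole cause, because 9 of 16 tested members (56.2%) exceeded both other libraries in exact binomial tests, but not for the 4 globin genes, of which 0% did, and GC content and length are excluded by the 100% of the 9 that remained so with the trends removed. A lower share of regulatory T cells in library 2 than in library 3 would raise all other markers alike only if the mix of other cells were the same. The B cell list had a median log2 ratio of library 2 to library 3 of -0.69, which argues against that case alone. With a different mix of other cells, a lower share stays open. Against library 1 a lower share was not tested and stays open. The median CPM of the B cell list was 34.5 in library 1 and 44.6 in library 2. RNA of neutrophils, erythroid and plasma cells in library 2 may be the source, but it cannot be told apart from other causes. Of 20 members 75.0% were highest in library 2, between the 80% and 50% set as bounds after the result was seen. That share restates the pattern and cannot separate its causes. Hba-a1, Hba-a2, Xbp1 and Mzb1 were highest in library 3 and Csf3r (7, 3 and 3 counts) in library 1 (Hba-a2 and Csf3r were chosen after their values were seen), 0 of 12 neutrophil, 2 of 10 erythroid and 4 of 6 plasma cell genes reached 1 CPM in every library, and how the cells were sorted is not given in the sources used here.

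Genes near 2 counts per coding base, the 86 with 1.6 or more, hardly differed between the libraries. Equal levels counted without a ceiling would follow depth, but the median log2 ratio of library 3 to library 1 was -0.0277 in them against -0.20 in genes under 0.2 counts per coding base. A candidate explanation is that at most 1 read per position and strand was kept, which would allow 2 counts per base. Yet 21 genes of at least 300 coding bases lay above 2 counts per coding base, up to 2.56. Such a limit over the coding sequence alone would not allow these. The median variance-to-mean ratio of the unscaled counts was 0.986 (bootstrap 0.458 to 1.41). It lay below the lowest of 200 simulations in which Poisson counts followed depth (7.15). A first bound of 0.693, for Poisson counts in equally deep libraries, lay inside that bootstrap interval and left the matter open. It was replaced after the result was seen because the libraries differ in depth. Any cause that stops counts from following depth would give such a low ratio, so the test does not single out this explanation. If it holds, levels of genes such as Lck, Cd3e and Ighm are understated and their agreement between libraries says little.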
